A study of Homo sapiens with 8 samples.

How the data were processed

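The series holds 8 RNA-seq libraries of the K1 thyroid cancer line, 4 untreated and 4 irradiated, grouped by their titles and treatment labels. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads, a stranded library kit was used, fragments near 300 bases were selected and libraries were amplified by PCR and read as pairs. The labels name 2 sequencing instruments as alternatives without saying which was used. All libraries carry 1 batch label. Per the submitters' processing notes, fastp, HISAT2, RSEM and DESeq2 were used with the GRCh38 build; their versions and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart.

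The deposited table lists 62703 genes, of which 33590 have 0 counts in all libraries and 20966 have no symbol. Its estimated counts per gene and library were deposited by the authors without normalization, and between 27.1% and 31.02% of nonzero values were not whole, as RSEM gives. The table also holds the authors' TPM values, scaled for transcript length and library size, and the authors' comparison as log2 fold changes, fold ratios and p-values with adjusted p-values. Genes without an adjusted p appear to be listed there at 1 (47969 genes, 14379 of them with nonzero counts). Gene lengths are those of the deposited table. Gene types, coordinates and GC content of the longest transcript came from GENCODE 29 (GRCh38), which held 58279 of the listed identifiers and may not be the annotation used for the counts; SOD2 and H2AC18 carry newer identifiers and have no coordinates here.

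Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (14937 genes), scaled by TMM and tested with edgeR's quasi-likelihood F test (R 4.3.3, edgeR 4.0.16, limma 3.58.1), irradiated minus control, two-sided, with no covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM with the SD over 4 libraries, and log2 CPM used a prior count of 2. A set of 28 gene lists was fixed before the data were examined; camera tested each against the other genes with a preset correlation of 0.01, with adjustment over the lists, and was repeated with an estimated correlation. Cholesterol synthesis and DNA replication held with the estimated correlation, and the other 6 lists that passed did not. Terms deposited per gene were tested with the one-sided Fisher's exact (hypergeometric) test for terms of 10 to 300 genes among tested genes with a term. Python 3 tools were SciPy and pandas.

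Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among passing genes with a symbol, a mean of at least 1 CPM and libraries that did not overlap between groups. From each list it took up to 3 passing members with the smallest adjusted p, with both directions where both passed. SLC5A5, CDKN1A, MDM2, ATM, CHEK1 and BRCA1 were always included. Some genes that met the rule are not reported here. In all 98 genes met the rule, of which 97 could be tested and 93 passed. Other members of lists and terms are named after their values were seen.

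Libraries of 1 group were compared by a chi-square over 13521 genes and differed by 4.18 to 22.0 per degree of freedom, beyond sampling noise, so none was counted as a repeat of another. Depth of 17167998 to 21068289 counts sets the precision: a count of 0 allows 3 counts. This limit for a count of 0 covers counting error only, and the counts carry no molecular identifiers.

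The fit was tested on simulated counts for the same comparison and 14937 genes, with 200 genes changed. It recovered 22% of genes changed 1.25-fold, 70% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, with 6.04% of calls false, and gave 0 calls and 0 lists when no gene was changed. Simulated genes were drawn independently, without correlation between genes and without trends in length or GC content. The 0 lists therefore do not show how camera behaves when members of a list vary together. Alternatives planned before the data were examined were RLE size factors, library size alone, DESeq2 (1.42.0), limma voom, no low-count filter, at least 1 CPM in 4 libraries, the replicate number as a block, each library left out, limma on log2(TPM + 1) and log2(TPM + 0.1), protein-coding genes alone, a test against a fold of 1.5, fry, and terms of genes passing at any size. Alternatives added after seeing the data were a correction by natural splines (5 degrees of freedom) of GC content and length per library, and leaving out irradiated 1 with irradiated 3 or control 3 with irradiated 1.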

Results

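Messenger RNA was sequenced from K1 cells, a human differentiated thyroid cancer line of papillary type, with and without radioiodine irradiation. The 8 libraries formed 2 groups of 4: untreated control cultures and irradiated cultures, all given the same batch label. Radioiodine emits ionising radiation, which breaks DNA. The activity given and the time between irradiation and RNA extraction are not given in the sources used here. Each library held between 17167998 and 21068289 estimated counts, and between 20741 and 22224 genes had at least 1 count. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

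The comparison asks how transcription in these cells differed after irradiation, and the series' title places the DNA damage response at its centre. As lists tested by camera, cholesterol synthesis, mitosis, MAPK output and NF-kB target genes were lower in irradiated cells. DNA replication genes and ribosomal protein genes were higher as lists. Of these 6 lists, cholesterol synthesis and DNA replication also passed with an estimated correlation between genes, and the other 4 did not. Most changes were small. Of 14937 genes tested, 1918 passed, 983 higher and 935 lower in irradiated cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Only 176 of these changed at least 2-fold, 80 upward and 96 downward, and 36 changed by significantly more than 1.5-fold (13 higher, 23 lower). At an unadjusted p under 0.05 there were 4147 genes. Of the genes passing 51.25% were higher, and with 1 library left out this share ranged from 45.46% to 51.51%. On the deposited TPM values, tested with limma on log2(TPM + 1), 630 genes passed, 235 higher and 395 lower, a change of unit, scaling and test together. The number passing fell to 1120 without control 1, 1120 without control 2, 1276 without control 4 and 1223 without irradiated 3. Without irradiated 4 the number rose to 2714. The number was 1151 without irradiated 1 and irradiated 3, the libraries with the highest GC slopes, where 446 were higher and 705 lower.

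Among genes whose libraries did not overlap between groups, the largest rises included squamous keratins and secreted peptides. KRT16, a keratin of activated and stratified epithelium (ENSG00000186832, GRCh38 chromosome 17, 41609778 to 41615899, minus strand), rose by 1.59 ± 0.11 log2 units (SE), from 11.5 ± 0.590 to 34.7 ± 4.83 CPM (SD, n = 4 each; edgeR adjusted p = 8.21e-08). KRT14, a basal epithelial keratin (ENSG00000186847, chromosome 17, 41582279 to 41586921), rose by 2.06 ± 0.24, from 1.58 ± 0.627 to 6.59 ± 1.09 CPM (edgeR adjusted p = 3.23e-05). GAST, the gastrin precursor, rose by 1.93, EDN2, which encodes endothelin-2, by 1.88, and CST6, a cysteine protease inhibitor, by 1.83. The others were RBFOX3 (1.73), HBA2 (1.71), ITGB7 (1.70), RPL21P16 (1.66) and CKMT1A (1.65). Most of these lay near 1 CPM: EDN2 went from 0.441 ± 0.0932 to 1.65 ± 0.336 CPM. Reads of KRT14, KRT16, HBA2, RPL21P16 and CKMT1A can be shared with near-identical copies, so their values are uncertain; CKMT1B, the twin of CKMT1A, was at -0.26 with an edgeR adjusted p of 0.685. CKMT1A and RPL21P16 lost their calls without irradiated 2 (adjusted p = 0.0601 and 0.0756) or irradiated 3.

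The largest falls combined an oxidase, a protease and several genes of low level. NOX5, a calcium-activated NADPH oxidase (ENSG00000255346, chromosome 15, 68930525 to 69062743, plus strand), fell by 1.94 ± 0.13 log2 units, from 55.2 ± 9.999 to 14.4 ± 2.33 CPM (n = 4 each; edgeR adjusted p = 8.21e-08). ADAMTS1, a secreted metalloprotease, fell by 1.74 (33.5 ± 8.75 to 9.97 ± 2.06 CPM), and the gap junction gene GJC1 by 1.48 (18.4 ± 4.44 to 6.63 ± 1.64 CPM). FAM72C (log2 change -3.07), FAM72B (-1.64), HMGN5 (-1.77), FJX1 (-1.63), NRIP1 (-1.47), ZBTB12 (-1.45) and MPDZ (-1.45) fell as well, each from under 4 CPM. FAM72 genes are near-identical copies, and how reads divided among them is uncertain. FAM72D also passed at -1.16, and FAM72A was at -0.57 with an edgeR adjusted p of 0.0803.

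**Figure D1:**
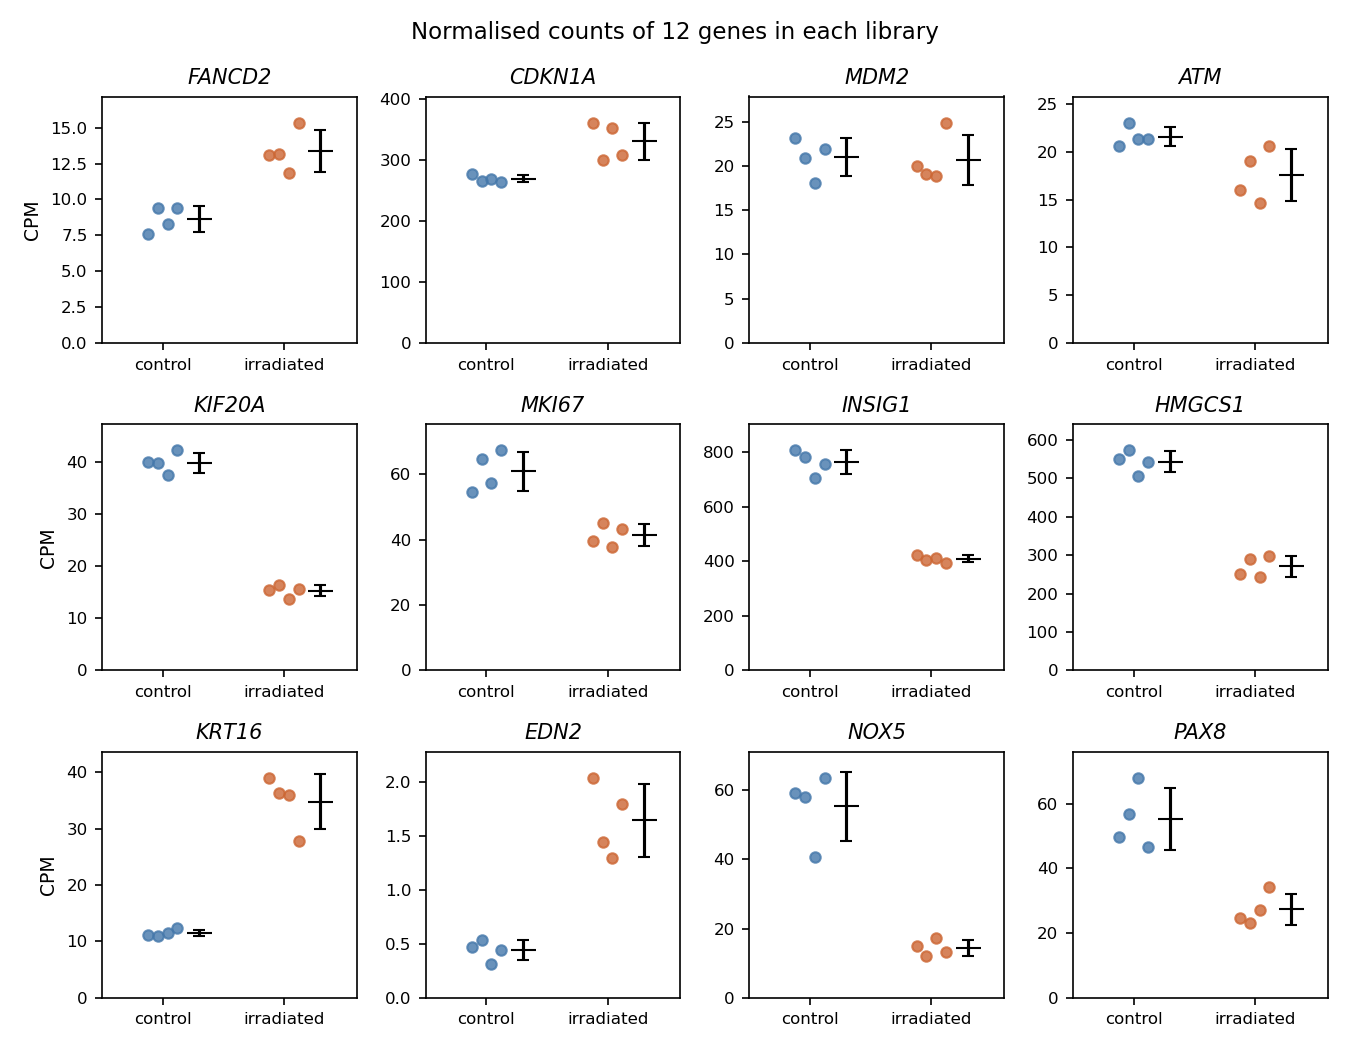
Normalised level in CPM (vertical axes, each from 0) of 12 genes in the 4 control (blue) and 4 irradiated (orange) libraries, with the mean and SD in black. KIF20A lies at 39.8 ± 1.90 CPM in controls and 15.3 ± 1.08 in irradiated cells, and MDM2 overlaps between the groups.

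Targets of p53, which respond to DNA breaks, moved in part. CDKN1A, the p21 cell cycle inhibitor (ENSG00000124762, chromosome 6, 36676460 to 36687339), rose by 0.30 ± 0.08 log2 units, from 269 ± 5.85 to 330 ± 31.0 CPM (n = 4 each; edgeR adjusted p = 0.0172). MDM2, a ubiquitin ligase gene and a classical member of the list, was at -0.02 ± 0.11 (edgeR adjusted p = 0.934), but on the deposited TPM values MDM2 lay upward, at 0.52 on log2(TPM + 1) and 0.57 on log2(TPM + 0.1), without passing. Of 34 measured p53 target genes, 6 rose, 2 fell and 26 did not pass; adjusted over the list alone, 6 rose and 2 fell. After a correction for GC content and length 11 rose and 3 fell, and the list did not pass (camera adjusted p = 0.0925). PLK3, a stress kinase, rose by 0.71 and FDXR, a mitochondrial reductase, by 0.59, with AEN, RPS27L and TRIAP1 the other rises. BBC3, which encodes the death protein PUMA, fell by 0.46, as did the death receptor gene TNFRSF10B. As a list, p53 targets did not pass (camera adjusted p = 0.0602; adjusted p = 0.487 with an estimated correlation). The list passed without control 1 (adjusted p = 0.0250) and without irradiated 2 (adjusted p = 0.0246). The CDKN1A call was lost without control 2, control 4, irradiated 1 or irradiated 3 (adjusted p up to 0.0634).

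Most members of the DNA repair and checkpoint lists did not pass, and those that passed changed by under 1 log2 unit. That was so for most genes: of 14937 tested 1918 passed, and 176 of these changed at least 2-fold. In homologous recombination, which repairs breaks from a sister chromatid, 2 of 24 measured genes rose and 22 did not pass. The nuclease subunit gene EME1 rose by 0.48. BRCA1 was at 0.20 ± 0.22 (edgeR adjusted p = 0.607). Of 19 Fanconi anaemia genes, FANCD2 (0.62) and FAAP20 (0.35) rose. In non-homologous end joining only MAD2L2 rose (0.29), out of 18. Among 24 damage checkpoint genes HUS1 rose (0.31), and 3 fell, the mitotic entry kinase gene WEE1 (-0.47) and the phosphatase gene CDC25B (-0.31) among them. ATM, the break-sensing kinase, was at -0.29 ± 0.11 (edgeR adjusted p = 0.0814), and CHEK1 at 0.03 ± 0.09 (edgeR adjusted p = 0.871). Base excision repair had 3 rises of 20 (FEN1, MPG and APEX2), and nucleotide excision repair 1 fall of 23 (UVSSA, -0.39).

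Of the 8 damage response lists, mismatch repair alone passed (4 of 19 higher, none lower; camera adjusted p = 0.00876). Its call was lost with an estimated correlation (adjusted p = 0.222). The members that rose were PCNA (0.44), RFC5 (0.38), RFC2 (0.36) and RPA2, which encode the sliding clamp, its loader and a single-strand binding protein, all also used in replication. Camera adjusted p was 0.185 for homologous recombination, 0.134 for the Fanconi list, 0.262 for base excision repair, 0.597 for nucleotide excision repair, 0.687 for checkpoint signalling and 1 for end joining. Checkpoint genes had a median of 0.03 but a mean of -0.04 and a downward test; end joining genes had a median of 0.01 and a mean of 0.01 against a downward test. Adjusted over the list alone, 2 recombination genes, 5 Fanconi genes, 6 mismatch repair genes and 0 end joining genes were higher. The same count was 1 higher and 3 lower for checkpoint genes, 3 higher for base excision and 1 lower for nucleotide excision repair. The HUS1 call was lost in each of the 8 fits that left out 1 library (adjusted p up to 0.157), those of EME1, MAD2L2 and APEX2 in 6, that of MPG in 5, RFC2 in 4, FAAP20 in 3 and WEE1 in 2. UVSSA lost its call without control 1 (adjusted p = 0.0562). After a correction for GC content and length, MAD2L2 (0.08; edgeR adjusted p = 0.418) and MPG (0.10; edgeR adjusted p = 0.232) lost their calls, and base excision repair had 2 genes higher and 1 lower.

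**Figure D2:**
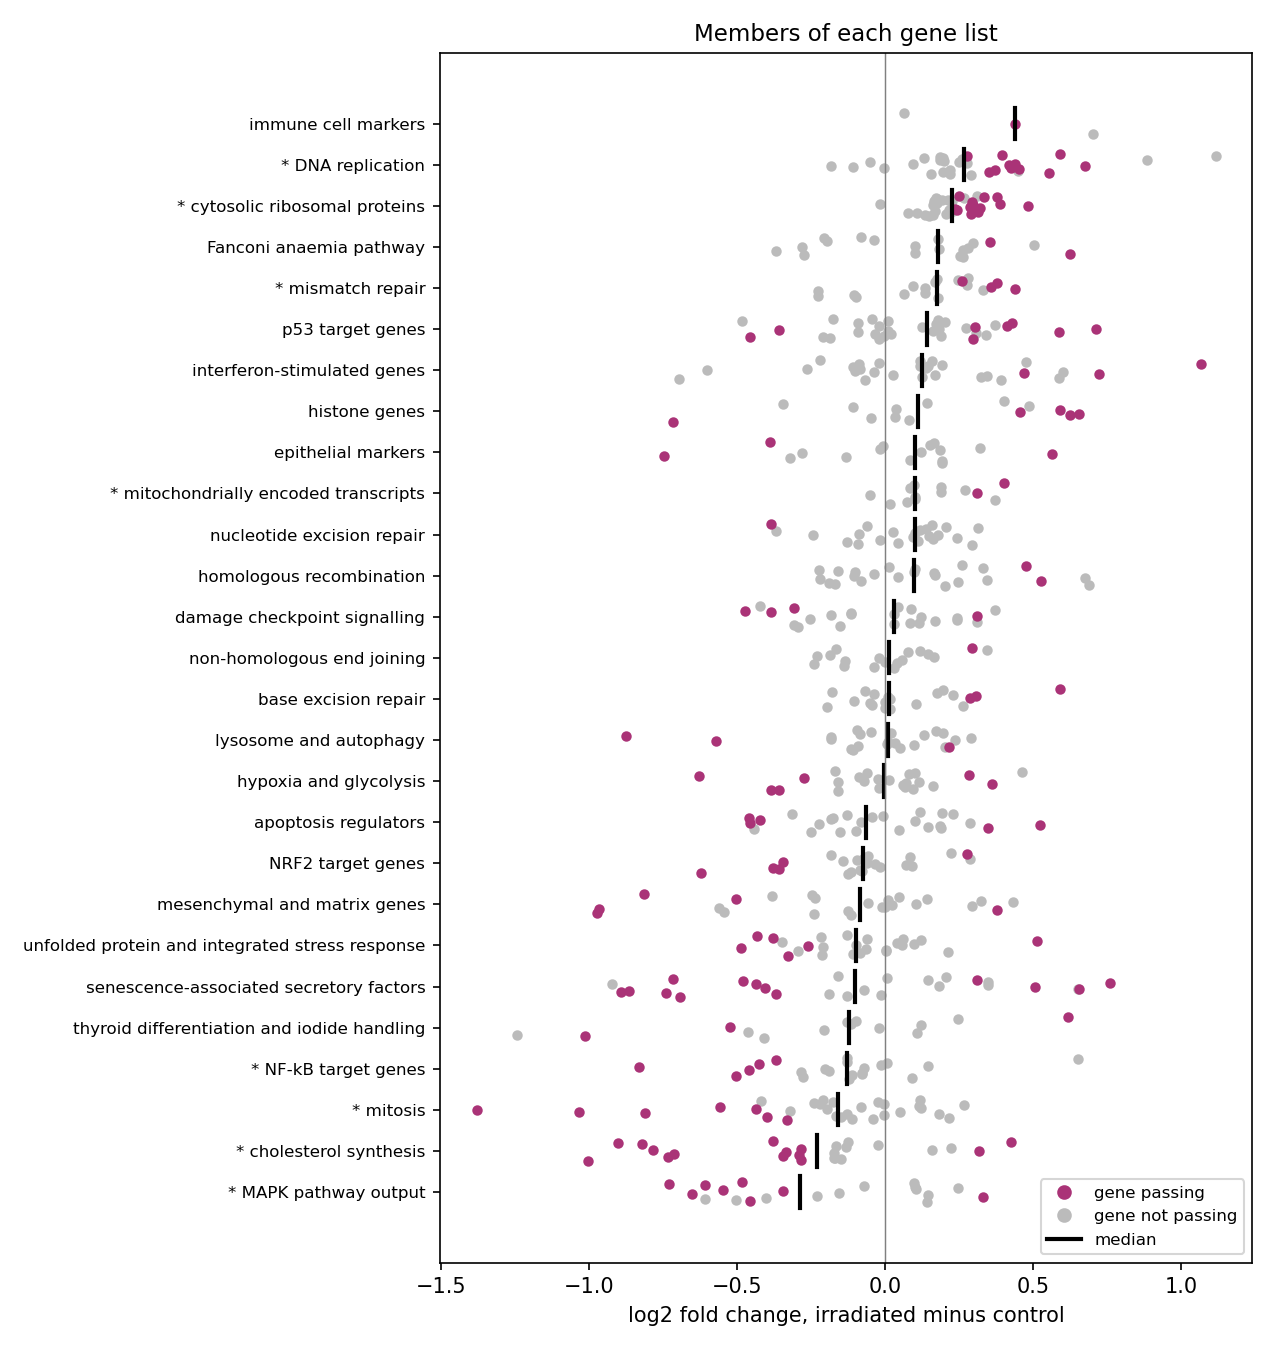
Log2 fold change (horizontal axis, irradiated minus control) of each measured member of 27 gene lists, 1 row per list ordered by median. Magenta points passed and grey ones did not, black bars are medians, and an asterisk marks lists passing camera with a preset correlation, of which DNA replication has a median of 0.27 and MAPK output one of -0.29.

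Some DNA replication genes rose and some mitosis genes fell. Of 32 replication genes, 11 rose and none fell, with a median of 0.27 (camera adjusted p = 2.03e-08; adjusted p = 0.0321 with an estimated correlation). MCM5, a subunit of the replicative helicase (ENSG00000100297, chromosome 22, 35400063 to 35425430), rose by 0.55 ± 0.10, from 48.0 ± 5.31 to 70.4 ± 9.66 CPM (n = 4 each; edgeR adjusted p = 0.00173). GINS2 rose by 0.68 and PCNA by 0.44, and the others were MCM7, CDC6, CDC45, ORC1, GINS4, CCNE1, E2F1 and FEN1. By adjustment over this list alone, 18 rose. Of 30 mitosis genes, 7 fell and none rose (median -0.16; camera adjusted p = 2.53e-05), a call lost with an estimated correlation (adjusted p = 0.316). KIF20A, a kinesin of the central spindle (ENSG00000112984, chromosome 5, 138178719 to 138187715, plus strand), fell by 1.38 ± 0.09, from 39.8 ± 1.90 to 15.3 ± 1.08 CPM (n = 4 each; edgeR adjusted p = 7.73e-08), the smallest p of any gene. CENPA, the centromeric histone, fell by 0.81 and the proliferation marker MKI67 by 0.56, with CENPF, CCNB1, AURKA and KIF23 the other falls. Within the list alone, adjustment left 11 lower.

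Cholesterol synthesis genes fell together. Of 24 measured genes 12 fell, 2 rose and 10 did not pass, with the same counts adjusted over the list alone (median -0.23; camera adjusted p = 9.74e-13; adjusted p = 0.0242 with an estimated correlation). HMGCS1, which makes the precursor of the pathway (ENSG00000112972, chromosome 5, 43289395 to 43313512), fell by 1.01 ± 0.08, from 543 ± 27.6 to 271 ± 28.1 CPM (n = 4 each; edgeR adjusted p = 7.90e-07). INSIG1, the sterol-sensing retention protein (ENSG00000186480, chromosome 7, 155297776 to 155310235), fell by 0.90 ± 0.07, from 762 ± 43.8 to 408 ± 12.9 CPM (n = 4 each; edgeR adjusted p = 6.88e-07). The master regulator gene SREBF2 fell too, and the reductase gene TM7SF2 rose by 0.32.

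Some genes of growth factor signalling output and some inflammatory targets were lower. Of 20 MAPK output genes, 7 fell and 1 rose (median -0.29; camera adjusted p = 1.33e-04), and the call was lost with an estimated correlation (adjusted p = 0.222). EPHA2, a receptor kinase, fell by 0.73, from 552 ± 88.9 to 333 ± 12.3 CPM (n = 4 each; edgeR adjusted p = 8.83e-05), and CCND1, which encodes cyclin D1, fell by 0.61. The feedback inhibitor gene SPRY4 rose by 0.33, a call lost without control 1 (adjusted p = 0.0508). Adjusted over the list alone, 10 fell and 1 rose. Of 21 NF-kB targets, 5 fell and none rose (camera adjusted p = 0.00876; adjusted p = 0.411 with an estimated correlation). They were NFKB1 (-0.50), SOD2 (-0.42), BIRC3 (-0.46), TNF and the chemokine gene CXCL1. Adjusted over the list alone, 6 fell and 1 rose. Of 26 senescence-associated secretory genes, 9 fell and 4 rose, or 9 and 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0524; adjusted p = 0.383 with an estimated correlation). It passed without control 2 (adjusted p = 0.018), control 3 (0.0464), irradiated 1 (0.0218) or irradiated 3 (0.023). CXCL5 fell by 0.87 and EREG by 0.72, whereas IGFBP3 rose by 0.76. The BIRC3 call was lost without control 2, control 4 (adjusted p = 0.1), irradiated 1 or irradiated 3.

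Some thyroid identity genes changed, and others could not be tested. For scale, 1918 of 14937 genes passed over all those tested. SLC5A5, the sodium-iodide symporter through which radioiodine enters thyroid cells (ENSG00000105641, chromosome 19, 17871973 to 17895174, plus strand), had 0 counts in 6 of the libraries, 1 in control 4 and 2 in irradiated 4, too few to test. A count of 0 allows up to 3 counts, or between 0.142 and 0.175 CPM at these depths, for counting error only. Of 25 thyroid genes 14 were measured, of which PAX8, DUOXA2 and TFF3 passed. PAX8, a thyroid lineage transcription factor (ENSG00000125618, chromosome 2, 113215997 to 113278950), fell by 1.02 ± 0.13, from 55.3 ± 9.50 to 27.3 ± 4.91 CPM (n = 4 each; edgeR adjusted p = 6.00e-05). DUOXA2, the maturation factor of a hydrogen peroxide-producing oxidase, fell by 0.52, and TFF3 rose by 0.62, a call lost after a correction for GC content and length (0.34; edgeR adjusted p = 0.0593). The list did not pass (camera adjusted p = 0.0524; adjusted p = 0.459 with an estimated correlation), but passed without control 1 (adjusted p = 0.0369) or irradiated 3 (0.0417), and adjusted over the list alone 4 fell and 1 rose.

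Some ribosomal protein genes and 2 mitochondrially encoded transcripts were higher, and both lists are of short genes. Of 36 cytosolic ribosomal protein genes, 14 rose and none fell (median 0.23; camera adjusted p = 1.55e-10; adjusted p = 0.316 with an estimated correlation). RPL37 rose by 0.48, RPLP2 by 0.39 and RPS19 by 0.38; adjusted over the list alone, 19 rose. Of 13 mitochondrial transcripts MT-CYB (0.40) and MT-ND6 (0.31) rose, 3 adjusted over the list alone (camera adjusted p = 0.00926; adjusted p = 0.459 with an estimated correlation). That call was lost without control 4 (adjusted p = 0.0767), and the MT-ND6 call without control 1 (edgeR adjusted p = 0.0766), control 4 or irradiated 3. Mitochondrial transcripts took 2.18% ± 0.181 of counts in controls and 2.56% ± 0.0812 in irradiated libraries, and ribosomal protein genes 8.24% ± 0.219 and 9.48% ± 0.274 (SD, n = 4 each; exact two-sided permutation p = 0.0286 for each, the smallest that 4 against 4 allow, and adjusted p = 0.0572 over 8 library measures).

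Gene length went with the group, on average, in the fold changes. Of 5 equal groups by length, the shortest (median 1050 bases) had a median log2 change of 0.14 and the longest (median 6932 bases) one of -0.12. Across 14937 genes, which are not independent replicates, Spearman's rho between length and log2 change was -0.332, and for GC content it was 0.20 over 14495 genes. In each library, log2 CPM less the gene's mean over the 8 libraries was fitted on log2 length. The slope was 0.0443 ± 0.00552 in controls and -0.0443 ± 0.0448 in irradiated libraries (SD, n = 4 each). The exact two-sided permutation p of the difference was 0.0286, with an adjusted p of 0.0572 over 8 library measures. Taking the mean of the 8 libraries as 0 sets the signs, so only the difference between groups can be read. The irradiated slopes ranged from -0.0797 to 0.0155, all below the controls, and that of irradiated 4 lay closest to them. The median length was 991 bases for the ribosomal list, 784 for mitochondrial transcripts, 2682 for replication, 2872 for mitosis and 2725 for cholesterol synthesis, against 2916 for all tested genes. After a correction for GC content and length, chosen once the trend had been seen, the ribosomal list had a median of 0.09 (camera adjusted p = 0.00128) and mitochondrial transcripts no longer passed (median 0.04; adjusted p = 0.613). RPLP2 (0.04; edgeR adjusted p = 0.643) and MT-ND6 (0.12; edgeR adjusted p = 0.402) lost their calls. RPL37, deposited with a length of 7573 bases, instead went from 0.48 to 0.63. The SD of log2 change among members grew with the correction, from 0.094 to 0.154 for the ribosomal list and from 0.138 to 0.166 for mitochondrial transcripts. The correction therefore does not show that length accounts for the rise of these 2 lists. Replication had a median of 0.27 (adjusted p = 2.63e-09), mitosis -0.16 (adjusted p = 0.00128) and cholesterol synthesis -0.30 (adjusted p = 6.30e-09).

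**Figure D3:**
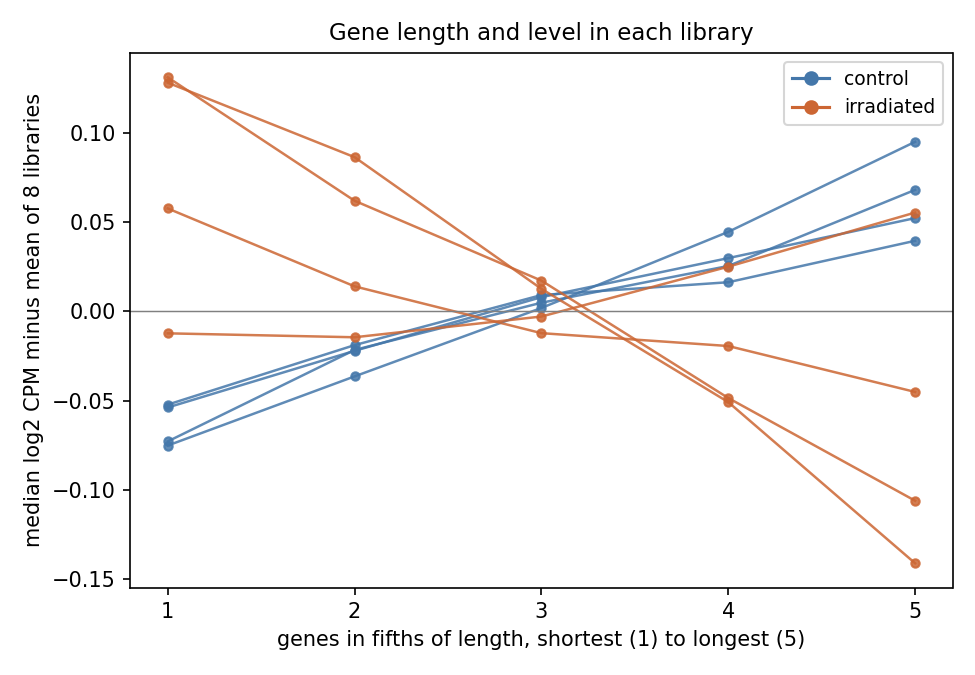
Median log2 CPM of genes in 5 equal groups by length, from shortest to longest, as the difference from the mean of the 8 libraries, with 1 line per library (blue, control; orange, irradiated). Medians of the shortest group run from -0.0751 to -0.0522 in controls and from -0.0123 to 0.131 in irradiated libraries.

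The remaining lists did not pass with all libraries. HMOX1 (-0.62) and SRXN1 (-0.36) fell and TXN (0.28) rose among 22 NRF2 targets (4 lower, 1 higher; camera adjusted p = 0.185). Of 25 unfolded protein and stress response genes 5 fell, HERPUD1 (-0.49) and PPP1R15A (-0.43) among them, and CHAC1 rose (0.51; adjusted p = 0.0901); the list passed without control 3 (0.00456) or irradiated 1 (0.0465). BNIP3 (-0.63) and SLC2A1 (-0.39) fell and ALDOA (0.36) rose among 24 hypoxia and glycolysis genes (4 lower, 2 higher; adjusted p = 0.558). OASL (0.72), IFI6 (0.47) and BST2 (1.07) were the interferon-stimulated genes that rose, of 29 (adjusted p = 0.0901). Of 14 histone genes 4 rose and 1 fell, H2BC12 (0.59) and H2AC18 (0.63) among the rises (adjusted p = 0.262). After a correction for GC content and length, H2BC12 (0.27; edgeR adjusted p = 0.158) and TXN (0.14; edgeR adjusted p = 0.112) lost their calls, and 1 histone gene was higher. BIK (0.52) and BAK1 rose and BBC3, XIAP (-0.42) and BIRC3 fell among 26 apoptosis regulators (adjusted p = 0.737). With 1 library left out, the calls of ALDOA (5 of 8 fits), TXN (3), PPP1R15A (3), BST2 (2) and IFI6 (1) were lost, with adjusted p up to 0.127. Adjusted over the list alone, these 6 lists gave 4 lower and 3 higher, 8 and 1, 4 and 2, 0 and 3, 1 and 5, and 4 and 3.

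Some markers of cell state rose and others fell, and most markers of other cell types could not be tested. KRT19 (-0.75) and ELF3 (-0.39) fell and CLDN3 (0.56) rose among 16 epithelial markers, with a median of 0.10 and a mean of 0.005 against a downward test (camera adjusted p = 1). CDH2 (-0.97), TNC (-0.81), SNAI2 and CCN1 fell and SNAI1 (0.38) rose among 24 mesenchymal and matrix genes (adjusted p = 0.0574). That list passed without control 3 (adjusted p = 0.0035), irradiated 3 (0.00498) or irradiated 4 (0.0276), and after a correction for GC content and length SNAI1 lost its call (0.26; edgeR adjusted p = 0.0972). SQSTM1, an autophagy receptor, fell by 0.88 and NPC1 by 0.57, while CTSL rose by 0.22, among 23 lysosome and autophagy genes, whose median was 0.01 and mean -0.03 (adjusted p = 0.438). Of 14 immune cell markers 3 were measured and CD68, also a lysosomal protein, rose by 0.44 (adjusted p = 0.0524; the list passed without control 1 at 0.0423, irradiated 1 at 0.049 or irradiated 3 at 0.0447). Of 8 endothelial markers VWF was measured, and it rose by 0.71, from 1.89 ± 0.310 to 3.10 ± 0.178 CPM (n = 4 each; edgeR adjusted p = 0.0269). Adjusted over the list alone, 3 epithelial genes rose and 4 fell, 2 mesenchymal genes rose and 5 fell, 2 lysosome genes rose and 2 fell, 2 immune markers rose and VWF rose. With 1 library left out, the calls of CTSL (7 of 8 fits), SNAI1 (6) and VWF (5) were lost, with adjusted p up to 0.143, 0.129 and 0.0772.

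Annotated terms of the genes that rose at least 2-fold were of filaments, keratins and serine peptidases. Of 2742 gene ontology terms 6 passed, led by intermediate filament (6 genes against 0.204 expected; Fisher's exact adjusted p = 1.29e-04), with KRT16, KRT14, KRT3, DES, NES and an unnamed keratin copy. The others were hair cycle, keratinization, cornification and 2 serine peptidase terms holding KLK11, KLK14, TMPRSS4, TPSAB1, TPSB2 and GZMB. The filament, hair and keratin terms all hold KRT14 and KRT16, which can share reads with near-identical copies, so these terms are not independent. After the GC content and length correction, 3 of 4 cornification genes passed. So did 4 of 6 genes of serine-type endopeptidase activity and 3 of 4 of serine-type peptidase activity, and all those of the other 3 terms. By the same one-sided exact test 0 of 320 KEGG pathways passed for the rises (12 at an unadjusted p under 0.05), and for the 2-fold falls 0 of 2742 terms (47 unadjusted) and 0 of 320 pathways (3 unadjusted).

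Groups separated in the overall structure. The first principal component of the 500 most variable genes held 30.8% of the variance and separated all 4 irradiated from all 4 control libraries; the second held 17.3%. By the authors' deposited comparison, 2157 genes had an adjusted p under 0.05, 1116 higher and 1041 lower. There the authors' deposited table marked 539 as significant, 205 higher and 334 lower, a mark that corresponded to a 1.5-fold limit. Of the genes passing in the edgeR test, 1876 also had an adjusted p under 0.05 in the authors' deposited table, all with the same sign, and 42 did not.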

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

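Tests of the splits, of the length slope, of the corrections and of the number of dividing cells were chosen after the results had been seen; the 2 tests on subsets of genes in the length trend were chosen before theirs.

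Of 210 groups of 4 values looked at, 11 had a library far from the others by its gap over the group's range, against about 1 in 20, or 10.5, by chance. Control 3 was that library in 7 of them. Mitochondrial transcripts took 1.909% of its counts, against 2.253% to 2.289% in the other controls (0.905). It lay toward the irradiated level for ADAMTS1 (20.4 CPM against 37.0 to 38.9, 0.897), GJC1 (11.7 against 20.4 to 20.95, 0.939), OASL (20.9 against 15.7 to 16.2, 0.890) and FAAP20 (37.0 against 31.7 to 32.1, 0.934). It lay away from it for FAM72B (5.16 against 3.33 to 3.52, 0.898) and EPHA2 (684.9 against 495.9 to 516.0, 0.894). Irradiated 4 was high for NRIP1 (1.98 CPM against 0.578 to 0.794, 0.846) and low for IGFBP3 (43.3 against 48.1 to 48.5, 0.906). Control 2 was low for ZBTB12 (1.51 against 2.17 to 2.24, 0.903), and irradiated 1 was high for BRCA1 (3.97 against 2.51 to 2.65, 0.900).

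The number of changed genes was set against other splits of the libraries. Among the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 1918 genes, and the highest other gave 3. For changes of at least 2-fold, again 1 split gave as many as 176, and the highest other gave 1. Every other split mixes both groups, so a group difference widens the spread within its sides and holds its count down. The test therefore cannot exclude a chance difference between the cultures or preparations of the groups.

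Short genes were higher and long genes lower on average after irradiation, least so in irradiated 4. Its slope on length (0.0155) lay below the control slopes (0.0366 to 0.0486). Against the mean of the 8 libraries, its shortest group (-0.0123) lay above the controls (-0.0751 to -0.0522). Its longest group (0.0553) lay within the control range (0.0395 to 0.0949). Library-to-library variation unrelated to the group stays open: all 4 irradiated slopes lay below all 4 controls (exact permutation p = 0.0286), but with 8 measures looked at the adjusted p was 0.0572. Ribosomal, mitochondrial and respiratory genes alone do not account for it, since without them the gap between the shortest and longest of 5 length groups was 0.248, against 0.26 over all genes. RNA integrity or library preparation that differed with the group stays open: the gap was 0.267 in genes of upper abundance and 0.248 in genes of lower abundance, which it requires, but group and preparation cannot be told apart: all libraries share 1 batch label, but the labels do not say which step it covers, and RNA integrity is not given. An effect of irradiation on transcripts by length stays open too and was not tested.

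DNA replication genes were higher and mitosis genes lower as lists. A GC content and length trend as the whole cause is argued against, since after the correction both lists passed with a largest adjusted p of 0.00128 and medians of 0.27 and -0.16. A lower share of dividing cells would lower both lists, and replication genes had a median of 0.268 upward. The mitosis call does not survive an estimated correlation (adjusted p = 0.316), so that side of the pattern is weaker. A shift of irradiated cells between cell cycle phases may fit and was not tested, as the data hold no measure of phase.

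Cholesterol synthesis genes were lower. A GC content and length trend is argued against as the whole cause (adjusted p = 6.30e-09 after the correction, median -0.30). Density or medium of the cultures was not recorded in the labels and stays open, as does irradiation itself.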

How the results depend on the processing

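The number of genes passing stayed within 1.5 times of 1918 with RLE factors, library size alone, DESeq2, voom, both low-count filters, protein-coding genes and the GC content and length correction, and all 1918 genes kept their sign in each fit on counts that tested them, except 5 after the correction. On TPM, 9 of them changed sign. The number passing fell to 630 and 632 on log2(TPM + 1) and log2(TPM + 0.1), where the share higher was 37.3% and 36.71% and the 2-fold count 46 and 114; the cause was not tested. With each library left out it ranged from 1120 to 2714, the 2-fold count from 131 to 254 and the share higher from 45.46% to 51.51%. Without irradiated 1 and 3, an alternative chosen after seeing the data like the correction and the other pair, these were 1151, 106 and 38.75%, and the cause was not tested. The share was 47.97% without a low-count filter and 48.82% without control 3 and irradiated 1. A test against a 1.5-fold change gave 36 genes by its stricter null. Without a size limit 55 GO terms and 14 KEGG pathways were enriched upward and 52 and 73 downward, as more genes entered.

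The replicate number as a block gave 2061 genes, and no list changed its call or direction. Same-numbered libraries did not deviate together (correlations 0.0377, 0.0444, -0.0351 and -0.0725, and only control 1 and irradiated 2, of the 8 libraries, deviated most like the library of their own number), so the numbers are not taken as pairs.

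Cholesterol synthesis and DNA replication passed in every setting. With an estimated correlation mismatch repair and MAPK output (adjusted p = 0.222), ribosomal proteins and mitosis (0.316), NF-kB targets (0.411) and mitochondrial transcripts (0.459) lost their calls. On TPM with pseudocounts of 1 and 0.1 mismatch repair (0.0651, 0.0641) and mitochondrial transcripts (0.307, 0.309) lost theirs. With fry NF-kB targets (0.0722) and mitochondrial transcripts (0.1) did not pass, and Fanconi genes (0.00355), immune markers (0.000286), interferon-stimulated genes (0.00808) and senescence-associated factors (0.0356) did. Fry tests whether a list changes at all, and not against the other genes as camera does. A pass by fry therefore does not show that a list stands out from other genes. After the GC content and length correction mitochondrial transcripts lost the call (0.613), Fanconi genes gained it (0.0385) and checkpoint genes turned upward (0.896). Recombination genes passed without irradiated 1 and 3 (0.0412), and p53 targets without a low-count filter (0.0154). With single libraries left out, adjusted p ranged from 0.0246 to 0.229 for p53 targets, from 4.08e-05 to 0.0767 for mitochondrial transcripts, from 0.841 to 0.984 for end joining and from 0.404 to 0.984 for epithelial markers. The last 2, never called, changed direction in some of these. End joining also did so with RLE (0.999), library size alone (0.947), DESeq2 (0.995), without irradiated 1 and 3 (0.947) and without control 3 and irradiated 1 (0.877), and epithelial markers with voom (0.861). Lists that had not passed gained a call in some settings, 9 of 27 without irradiated 1 and 3 and 5 without a low-count filter. With 1 library left out the lowest adjusted p was 0.0035 for mesenchymal, 0.00456 for unfolded protein response, 0.018 for senescence-associated, 0.0369 for thyroid and 0.0423 for immune genes. The cause of these changes was not tested.

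Of 93 passing named genes, 68 kept the call in every fit that left out 1 library and none changed sign; after the correction 8 of 97 named genes lost their call. Genes that did not pass changed sign: MDM2 was at 0.52 and 0.57 on the 2 TPM scales, 0.064 without irradiated 1 and 3, and from -0.13 to 0.028 with single libraries left out. CHEK1 was at -0.11 and -0.12 on TPM, -0.0029 without control 3 and irradiated 1, and from -0.021 to 0.071 with single libraries left out. BRCA1 was at -0.10 and -0.16 on TPM. On log2(TPM + 1) 42 of 97 named genes lost their call. Depth limits genes near 1 CPM, and simulated 1.5-fold changes were recovered in 70% of cases.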

Other observations

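A list of fatty acid and other lipid genes was tested with a prediction written before its values were seen. The terms were planned, and single genes here are named after their values were seen.

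Terms tested on all passing genes held more rises than expected for respiration, and more falls than expected for matrix, inflammation and patterning. Of 118 oxidative phosphorylation genes 44 rose, against 11.2 expected (one-sided Fisher's exact adjusted p = 1.85e-14), many of them subunits of NADH dehydrogenase. These genes are short (median 1111 bases), and 23 of the 44 passed after the GC content and length correction. Of 89 genes of the TNF signalling pathway 22 fell, against 6.43 expected (adjusted p = 6.01e-05), among them IL6, JUN, JUNB, LIF and VCAM1, and 20 of them passed after the correction. Of 134 extracellular matrix organization genes 27 fell, against 8.67 expected (adjusted p = 6.89e-05), laminin genes LAMA5 and LAMC1 among them, and 24 passed after the correction. Of 69 skeletal system development genes 20 fell, against 4.46 expected (adjusted p = 1.02e-05), with HOXA10, HOXA11, HOXA13 and HOXB4, and 16 passed after the correction. Genes of the matrix and skeletal terms are long (medians 4197 and 3699 bases, against 2916 for all tested genes). Falls numbered 344 in the longest of 5 length groups and 72 in the shortest, which the expected counts do not allow for. Enrichment of the terms was not retested after the correction.

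Some genes outside the lists fell. TXNIP, a regulator of glucose uptake and redox balance, fell by 1.117 log2 units from 891 ± 45.4 to 411 ± 30.3 CPM (n = 4 each; edgeR adjusted p = 8.55e-08). FOXO3, a stress-responsive transcription factor, fell by 0.89 (edgeR adjusted p = 1.51e-06), and AXL, a receptor kinase, fell by 1.17 (edgeR adjusted p = 3.18e-06). GDF15, a member of the p53 target list, was at -0.19 with an edgeR adjusted p of 0.316.

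A hypothesis is that the fall in cholesterol synthesis genes belongs to a wider fall of lipid synthesis genes under sterol control. The prediction was that 15 genes not looked at before, chosen as fatty acid synthesis genes, would be lower as a list. The list also holds TMEM97, LPIN1 and PNPLA3, lipid genes that do not make fatty acids and that did not pass. Of 14 measured, 4 fell (ELOVL5 by 0.90, FADS1 by 0.73, ACSS2 and MID1IP1), none rose, and the median was -0.19 (camera p = 1.82e-05; p = 0.00386 with an estimated correlation). ACACA, FASN, SCD and ELOVL6, which are not in this list, also fell in the same libraries, so the test is not an independent one. The list was not retested after the GC content and length correction. The result is consistent with the hypothesis, and does not tell whether irradiation or culture conditions set it.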
